A study of Mus musculus with 8 samples.

How the data were processed

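RNA of the mouse ESC line CGR8 was measured on Affymetrix MoGene 1.0 ST arrays in 4 groups of 2 arrays: WT and PML KD ESCs at day 0, and WT and PML KD EBs at day 4. Per the labels, the PML hairpin was delivered with a lentiviral vector and infected cells were selected with puromycin. The protocol also mentions viruses of the empty vector, while the control group is labelled WT, so whether the control cells carried the empty vector is not given in the sources used here.

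The deposited array table holds linear intensity values that the authors had summarised to 1 value per probe set, 35556 in all. Per the submitters' processing notes the Transcriptome Analysis Console was used, and the background correction and normalization are not given in the sources used here. The array medians run from 169 to 199 in linear signal, so the deposited intensity values are not exactly quantile normalized over these arrays. A deposited workbook holds log2 values per Ensembl gene that the authors computed over constitutive exons, per the file headers. Its mean per array is 8.29 to 8.30 at day 0 and 8.06 to 8.08 at day 4, as if the days had been normalized apart, so its comparisons across days were made only after quantile normalization. The 4 columns of group means in the workbook were not used here. Of its 24451 genes 19036 were matched to a probe set of the array table, and the correlation between the tables lay between 0.888 and 0.93 per array.

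The deposited intensity values were turned to log2 with no added constant and no further scaling. The platform table lists 23410 of the 35556 probe sets, 21789 with 1 gene symbol and 1621 with several, and 12146 are not listed. Only probe sets with 1 symbol were used, and for the 999 genes with more than 1 the probe set with the highest mean was taken, which left 19938 genes. The precision follows from the arrays of a group: the SD of a single array, from the difference within pairs over all genes, was 0.107 to 0.131 on the log2 scale. Deviations within groups correlated from -0.082 to 0.085 between the 6 pairs of groups, so the replicate numbers were not taken to pair the samples.

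All 8 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 group means, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p under 0.05. A gene that passed is said to have risen, fallen or changed. The 5 contrasts were PML KD minus WT at day 0 and at day 4, day 4 minus day 0 in WT and in PML KD, and the difference of these changes. Each ± is the SE of the fitted difference. In simulated data made from these arrays, 5 of 68 genes changed by 0.3, 48 of 66 changed by 0.5 and 65 of 66 changed by 1 on the log2 scale were called, with 10 false calls among 19938 genes. Only these few genes were changed, in PML KD EBs alone. In the real contrasts far more genes passed (5705 at day 4), which loosens the adjusted threshold. These rates therefore do not give the detection limit of the real contrasts.

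There were 33 gene lists with 775 genes, of which 704 were measured, and 32 lists were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists of a contrast. The lists are the knockdown target, PML nuclear body components, core and naive pluripotency, formative and primed epiblast, 2-cell-like state, primitive streak and mesendoderm, early and lateral mesoderm, cardiac muscle, haemato-endothelial, definitive endoderm, primitive and visceral endoderm, neuroectoderm, surface ectoderm and epithelial keratins, trophectoderm, germ line, interferon response, p53 targets, TGF-beta and Nodal targets, BMP targets, LIF and STAT3 targets, Wnt targets, epithelial-mesenchymal transition, fibroblast markers, cell cycle, apoptosis regulators, glycolysis and hypoxia, cholesterol synthesis, unfolded protein and amino acid stress, Polycomb and DNA methylation machinery, imprinted genes, Y-linked, HOX cluster and ribosomal proteins. Camera was repeated with the correlation estimated from the residuals, and fry was run as another set test. Adjustment over a list alone was also made.

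The lists, contrasts, tests, thresholds, alternatives and the rule for naming genes were written before the data were examined. Genes named are Pml, then for each knockdown comparison and for WT over time the 10 largest rises and 10 largest falls among genes that passed with both arrays of a group beyond both of the other. PML KD over time takes the genes named in WT, and the difference of changes the 10 largest in each direction. Up to 4 members per list with the smallest adjusted p are named as well, and a fixed set of pluripotency and lineage genes whether they passed or not. Genes whose symbol is not in the platform table are not analysed here. The text names a selection of these. Predicted or unnamed genes (symbols of the Gm, Rik or LOC kind) are counted but not named or ranked.

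Chromosome positions came from the workbook (19036 genes), chromosomes 1 to 19 and X were compared over the 9574 of these with a mean signal above the median of all genes, and random gene sets were drawn 1000 times for each chromosome. The alternatives were the workbook values, quantile normalization, a shift of each array to the same median, filters on genes above the 50th or 25th percentile of signal in a group, the mean of all probe sets of a gene, eBayes with trend and robust settings, array weights, a fit to only the 4 samples compared, the replicate number as a block, leaving out each array, and stricter thresholds. A fit without the PML KD day 0 arrays was added after the data were seen. Scan dates or slides are not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.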

Results

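The promyelocytic leukaemia protein (PML), the scaffold of PML nuclear bodies, was depleted with a stably expressed short hairpin RNA in CGR8, a mouse embryonic stem cell (ESC) line that grows without feeder cells. RNA was taken from WT and PML knockdown (KD) cells at day 0, as ESCs kept in leukaemia inhibitory factor (LIF), and at day 4 as embryoid bodies (EBs), aggregates that differentiate after LIF is withdrawn. Each of the 4 groups was measured on 2 Affymetrix mouse gene arrays, 8 in all, and 19938 genes were tested. The median linear signal of an array lay between 169 and 199. Over these genes the arrays of a group correlated at 0.996 to 0.997, and the mean correlation between groups ran from 0.949 (PML KD day 0 against WT day 4) to 0.983 (WT day 4 against PML KD day 4). Differences are on the log2 scale with the standard error (SE) of the limma fit, n = 2 arrays per group. The number of arrays limits the precision, and nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

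The Pml transcript was examined first, as the target of the hairpin. At day 0 it lay at 11.70 and 11.68 in the WT arrays and at 11.10 and 11.07 in the PML KD arrays, a difference of -0.60 ± 0.08 (adjusted p = 0.000317). The size of this fall depended on the scaling. Quantile normalization gave -0.455 (adjusted p = 0.00192), the workbook after it -0.402 (adjusted p = 0.0114) and a median shift -0.826. Pml is among the bright genes, which as a whole were lower in this comparison. At day 4 it was 10.88 and 10.84 in WT EBs and 10.54 and 10.69 in PML KD EBs, a difference of -0.24 ± 0.08 (adjusted p = 0.0451). This call was lost when any 1 of the 8 arrays was left out (adjusted p from 0.0527 to 0.243) and when the arrays were shifted to a common median (-0.13, adjusted p = 0.246), while quantile normalization gave -0.34 (adjusted p = 0.0145) and the workbook after it -0.35 (adjusted p = 0.0314). Pml also fell during differentiation, by 0.83 ± 0.08 in WT and by 0.47 ± 0.08 in PML KD. Transcripts of the Y chromosome set the PML KD day 0 arrays apart from the other 6. Eif2s3y, a translation initiation factor gene, lay at 5.20 and 4.95 there and between 9.86 and 10.20 on all other arrays. Uty, a histone demethylase gene, lay at 5.40 and 5.77 against 9.03 to 9.38.

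**Figure D1:**
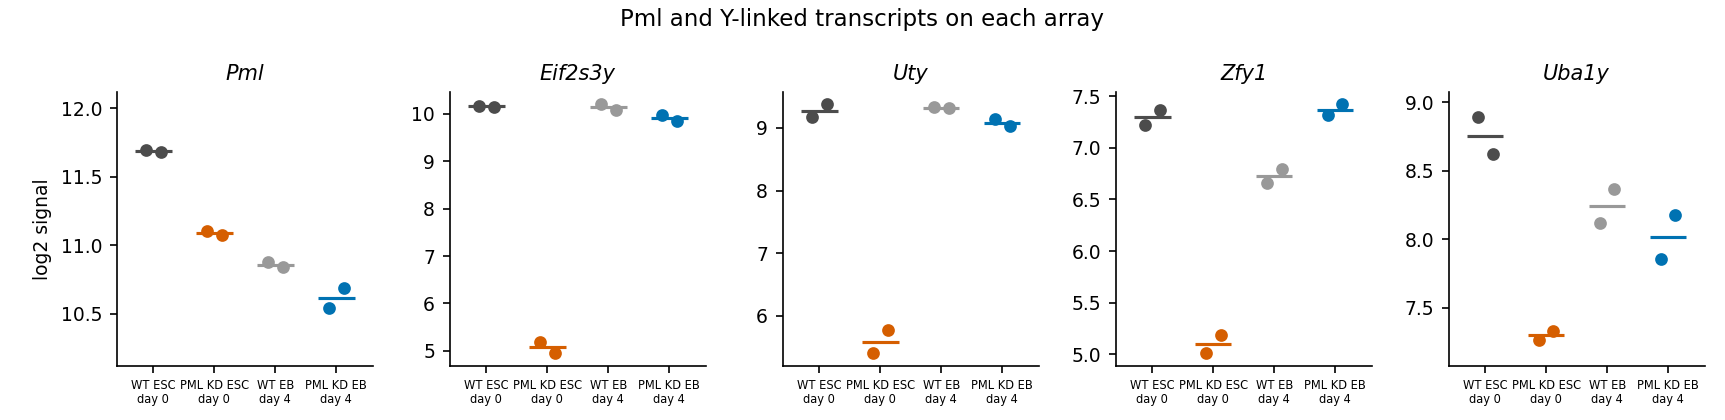
Log2 signal of Pml and of 4 Y-linked transcripts (vertical axes, each with its own range) in the 4 groups, with 1 point per array and a line at the mean of the 2 arrays. Pml was lower in PML KD than in WT at day 0 by 0.60 as deposited, and Eif2s3y and Uty were near 5 to 6 only in the PML KD day 0 arrays.

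The first comparison asked which transcripts differ between PML KD and WT in undifferentiated ESCs. The PML KD day 0 arrays also stand apart in Y-linked transcripts and in genes of chromosomes 8 and 14, as described below. An effect of the knockdown therefore cannot be told apart from other differences between these day 0 cultures. Targets of LIF and of its transcription factor STAT3, the pathway that keeps mouse ESCs self-renewing, were lower in PML KD ESCs: 17 of 24 measured members fell and 3 rose (18 and 3 adjusted over the list alone), with a median of -0.77. Fos, an immediate early transcription factor, fell by 2.83 ± 0.07 (adjusted p = 6.63e-07). Socs3, the feedback inhibitor of the pathway, fell by 2.39 ± 0.12 (adjusted p = 7.28e-06), and Zfp36, an mRNA decay factor, fell by 1.98 ± 0.09 (adjusted p = 4.3e-06). The gene set test camera placed the list below other genes (adjusted p = 9.51e-06), with adjusted p = 0.263 with an estimated correlation. Several core pluripotency factors were lower as well. Sox2 fell by 0.67 ± 0.08, Pou5f1 fell by 0.62 ± 0.08 and Nanog fell by 0.48 ± 0.07. Esrrb (-0.19 ± 0.07, adjusted p = 0.051) and Zfp42 (0.07 ± 0.07, adjusted p = 0.4) did not pass, although Esrrb did after a median shift (-0.41, adjusted p = 0.00132) and Zfp42 after quantile normalization (adjusted p = 0.00892). Klf4 fell by 0.73 ± 0.09 in the array table but was at 0.07 (adjusted p = 0.703) in the workbook values after quantile normalization. Of 35 core and naive pluripotency genes 19 fell and 9 rose (20 and 10 adjusted over the list alone; camera, adjusted p = 0.0313, and adjusted p = 0.515 with an estimated correlation). After quantile normalization 15 fell and 12 rose, and the median moved from -0.31 to -0.14 (camera, adjusted p = 0.891). The list also lost its call without PML KD ESC replicate 1 (median -0.30, adjusted p = 0.092). Among the falls were Eras, a Ras-like gene of ESCs, at -2.04 ± 0.09 and Lin28a, an RNA-binding regulator of pluripotency, at -1.20 ± 0.08.

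Transcripts of the 2-cell-like state, a rare fraction of ESCs with features of the early embryo, fell for 12 of 13 measured members (the same count adjusted over the list alone). Camera gave adjusted p = 4.98e-06, and adjusted p = 0.263 with an estimated correlation. Pramel6 fell by 1.84 ± 0.11, to under the 25th percentile of signal on both PML KD arrays, and Usp17lb fell by 1.30 ± 0.09. Genes of the formative and primed epiblast, the next stage of the embryo, went both ways, 11 rising and 8 falling of 26 (camera, adjusted p = 0.989). The growth factor Fgf5 rose by 1.15 ± 0.16 and Enpp3 by 1.39 ± 0.07, while the homeobox factor Otx2 fell by 0.91 ± 0.08 and the DNA methyltransferase Dnmt3b fell by 1.36 ± 0.10. Feedback targets of Nodal rose, Lefty1 by 1.56 ± 0.08, Lefty2 by 1.27 ± 0.11 and Nodal itself by 0.59 ± 0.07. In the TGF-beta and Nodal list 10 of 23 members rose and 5 fell, with a median of 0.16 that was -0.07 after a median shift (camera, adjusted p = 0.272). The BMP-responsive inhibitors of differentiation fell, Id2 by 2.19 ± 0.09, Id3 by 1.17 ± 0.08 and Id1 by 0.93 ± 0.08. In the BMP list 5 of 17 members fell and 2 rose, the median was 0.04 (-0.16 after quantile normalization) and the mean -0.25 (camera, adjusted p = 0.272). Of the lineage factors, Eomes of the primitive streak fell by 1.51 ± 0.08, Gata6 of the endoderm fell by 0.63 ± 0.15 and Pax6 of the neuroectoderm rose by 0.89 ± 0.07. The call of Gata6 ended without WT ESC replicate 2 (-0.45, adjusted p = 0.0599). Mixl1 (0.05 ± 0.09), Mesp1 (0.15 ± 0.11), Kdr (-0.10 ± 0.12), Gata4 (0.13 ± 0.08), Foxa2 (-0.08 ± 0.12), Sox1 (-0.11 ± 0.11) and Nes (-0.02 ± 0.12) did not pass. Sox17 (0.41 ± 0.19) did not pass either, but was at 0.73 (adjusted p = 0.00512) without WT ESC replicate 1 and at -0.42 (adjusted p = 0.0192) in the workbook values after quantile normalization. Of the genes that did not pass, Kdr did after quantile normalization (-0.37, adjusted p = 0.0377) and in the workbook (-2.03, adjusted p = 0.00245). Foxa2 passed without PML KD ESC replicate 1 (adjusted p = 0.0493) and in the workbook values after quantile normalization (-0.28, adjusted p = 0.0353), where Gata4 passed too (0.33, adjusted p = 0.0459), and Sox1 passed after a median shift (adjusted p = 0.0334).

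Besides the Y-linked list, camera called 5 further lists lower in PML KD ESCs, in a comparison where bright genes as a whole were lower (the brightest of 10 groups by mean signal had a median of -0.247). None of these 5 lists passed after quantile normalization (camera, adjusted p from 0.0728 to 0.735). Ribosomal protein transcripts fell for 19 of 21 measured members and rose for 1 (20 and 1 adjusted over the list alone), while 10 fell and 1 rose after quantile normalization. Camera gave adjusted p = 4.98e-06, and adjusted p = 0.263 with an estimated correlation. Rpl8 fell by 0.98 ± 0.07 and Rps15 fell by 0.74 ± 0.08. Components of PML nuclear bodies other than Pml fell for 14 of 22 members and rose for 1 (16 and 1 adjusted over the list alone; camera, adjusted p = 0.00068, and adjusted p = 0.281 with an estimated correlation). The autophagy receptor Sqstm1 was at -0.87 ± 0.07 and the histone chaperone Daxx at -0.75 ± 0.09. In the cell cycle list 21 of 41 members fell and 4 rose (adjusted p = 0.00132, and adjusted p = 0.281 with an estimated correlation). The cyclin Ccnd3 fell by 1.12 ± 0.09 and the replication helicase subunit Mcm4 fell by 0.76 ± 0.07, while Ccnd1 rose by 1.04 ± 0.07. Glycolysis and hypoxia genes fell for 16 of 30 members and rose for 6 (adjusted p = 0.0288, and adjusted p = 0.281 with an estimated correlation). The glycolytic enzymes Pgk1 and Pgam1 were at -1.79 ± 0.07 and -1.06 ± 0.08, and the oxidoreductase Ero1a at 1.16 ± 0.07. Of the Polycomb and DNA methylation machinery 10 of 26 members fell and 3 rose (adjusted p = 0.0288, and adjusted p = 0.505 with an estimated correlation). Dnmt3l, a cofactor of de novo methylation, fell by 1.74 ± 0.08, the Polycomb ligase Rnf2 fell by 1.24 ± 0.08, and the demethylation enzyme Tet1 rose by 0.82 ± 0.08. Without PML KD ESC replicate 1 the glycolysis list (median -0.26, adjusted p = 0.0651) and the Polycomb list (median -0.15, adjusted p = 0.0904) lost their calls.

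Among the 10 largest rises of named genes at day 0 were Mir15a (2.24 ± 0.08), the cell adhesion molecule Ncam1 (2.11 ± 0.10), the Wnt acyltransferase Porcn (2.10 ± 0.09), the guidance cue Ntn1 (2.06 ± 0.08) and the releasing hormone Trh (2.00 ± 0.07). The largest falls were Eif2s3y (-5.09 ± 0.10), Spink10 (-5.08 ± 0.19), Uty (-3.69 ± 0.13) and the granule proteoglycan Srgn (-3.47 ± 0.07). Eif2s3y, Spink10 and Uty lay under the 25th percentile of signal on both PML KD day 0 arrays, so the low end of the signal range limits the size and order of these falls. In the Y-linked list 4 of 8 measured genes fell and the other 4 did not pass (camera, adjusted p = 0.0326, and adjusted p = 0.281 with an estimated correlation). Of these other 4, all but Sry lay under the 25th percentile of signal on every array, WT included, and could not show a fall. Chromosomes were compared over the 9574 placed genes with a mean signal above the median. In the same arrays the 529 such genes of chromosome 8 had a median difference 0.253 above that of other chromosomes and the 308 of chromosome 14 one 0.187 above it (0.254 and 0.183 after quantile normalization). Before that normalization, random gene sets of the same sizes reached 0.1 and 0.129. Fibroblast markers were the called list that rose, with 9 of 18 rising and 1 falling (camera, adjusted p = 0.0288, and adjusted p = 0.505 with an estimated correlation; adjusted p = 0.104 after quantile normalization). That call ended without WT ESC replicate 2 (median 0.23, adjusted p = 0.0509) and without PML KD ESC replicate 1 (median 0.23, adjusted p = 0.0617). In all, 10432 genes (52.3%) changed, 5477 higher and 4955 lower in PML KD. Of these 922 changed at least 2-fold, 229 higher and 693 lower (873 after quantile normalization, 278 and 595, and 1550 after a median shift, 98 and 1452). Of the changed genes 52.5% were higher as deposited, 38.6% after quantile normalization (3379 higher and 5379 lower) and 21.5% after a median shift (2032 and 7414). The median of all genes was 0.085 as deposited, -0.056 after quantile normalization and -0.14 after the shift. Of the 10 lists that camera called, the 2-cell-like (adjusted p = 1.27e-05) and LIF and STAT3 lists (adjusted p = 0.00285) also passed after quantile normalization, and the others had adjusted p from 0.059 to 0.891. Cholesterol synthesis genes, 10 of 20 rising and 5 falling, passed only after that normalization (adjusted p = 0.0297, and 0.272 before).

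**Figure D2:**
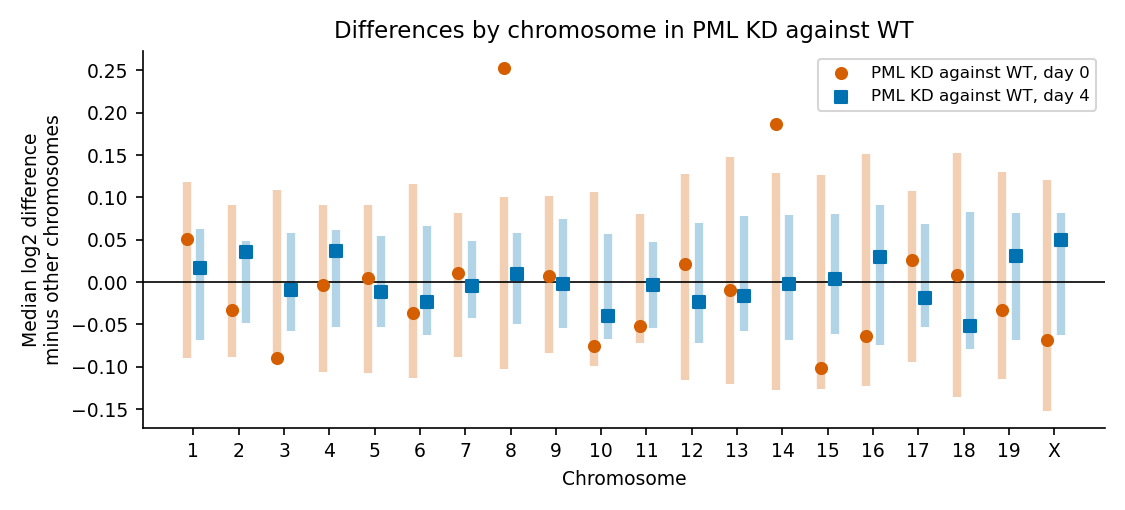
Median log2 difference between PML KD and WT for the genes of each chromosome with above-median signal, minus that of such genes on all other chromosomes (vertical axis), at day 0 (circles) and day 4 (squares). Pale bars give the range of 1000 random gene sets of the same size, and chromosomes 8 (0.253) and 14 (0.187) lay above it at day 0.

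The second comparison asked how PML KD EBs differ from WT EBs after 4 days of differentiation. Genes of the primitive and visceral endoderm, the extraembryonic layer that surrounds the embryo and secretes serum proteins, were lower in PML KD EBs: 34 of 36 measured members fell, 20 of them at least 2-fold, and none rose (the same counts adjusted over the list alone), with a median of -1.10. Alpha-fetoprotein, Afp, fell by 2.82 ± 0.08 (adjusted p = 3.06e-06). The apolipoproteins Apoa1, Apoa4 and Apob were at -2.81 ± 0.12, -2.78 ± 0.10 and -2.65 ± 0.10, and the endoderm transcription factors Gata6 and Gata4 at -1.06 ± 0.15 and -0.88 ± 0.08. The list passed with the preset correlation (camera, adjusted p = 2.14e-23) and with the estimated one (adjusted p = 0.0304 with an estimated correlation). Part of the primitive streak list was lower too: 8 of 22 members fell, 1 rose and 13 did not pass (camera, adjusted p = 0.00133, and adjusted p = 0.46 with an estimated correlation). Cer1, a secreted antagonist of Nodal, fell by 2.51 ± 0.08 and Eomes fell by 1.11 ± 0.08. Lhx1 fell by 0.91 ± 0.10 and Cyp26a1, which degrades retinoic acid, fell by 1.00 ± 0.11. In the definitive endoderm list 7 of 16 fell and 2 rose (adjusted p = 0.0356, and adjusted p = 0.238 with an estimated correlation), with Foxa2 at -0.73 ± 0.12 and Cxcr4 at -0.60 ± 0.09. It lost its call without PML KD EB replicate 2 (median -0.18, adjusted p = 0.0711). Sox17, an endoderm factor in both lists of endoderm, fell by 0.66 ± 0.19 (adjusted p = 0.0338). After a median shift it was at -0.54 and did not pass (adjusted p = 0.0596), and it did not pass when any 1 of the 4 EB arrays was left out: at -0.68 and -0.64 without WT replicate 1 or 2 (adjusted p = 0.0951 and 0.115), and at -0.80 and -0.52 without PML KD replicate 1 or 2 (adjusted p = 0.0611 and 0.182).

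Several naive pluripotency genes were higher in PML KD EBs. Nanog rose by 1.15 ± 0.07 (adjusted p = 3.92e-05), Nr5a2 by 1.30 ± 0.07, Jam2 by 1.55 ± 0.13 and Esrrb by 0.83 ± 0.07. Pou5f1 fell by 0.24 ± 0.08 (adjusted p = 0.0484) and Klf4 fell by 0.35 ± 0.09, and both calls ended after a median shift (-0.13, adjusted p = 0.274, and -0.23, adjusted p = 0.0963) and in the workbook as deposited (adjusted p = 0.13 and 0.0762). With the replicate block and with only the 4 samples compared, Pou5f1 did not pass either (limma, adjusted p = 0.065 and 0.063). The call of Pou5f1 also ended without any 1 of the 4 EB arrays or of the WT ESC arrays (-0.28 to -0.21, adjusted p from 0.0758 to 0.198). That of Klf4 ended without WT EB replicate 1 (-0.25, adjusted p = 0.117) and without PML KD EB replicate 1 (-0.34, adjusted p = 0.0952) or replicate 2 (-0.35, adjusted p = 0.0862). Sox2 (0.10 ± 0.08) did not pass. Zfp42 rose by 0.68 ± 0.07 in the array table and was at -0.16 (adjusted p = 0.473) in the workbook. Of the 35 genes 17 rose and 8 fell, a count that did not move when adjusted over the list alone (camera, adjusted p = 0.00682, and adjusted p = 0.46 with an estimated correlation). Trophectoderm markers rose for 14 of 20 members and fell for 2 (camera, adjusted p = 4.11e-07, and adjusted p = 0.138 with an estimated correlation). Rises included the keratin Krt7 at 1.86 ± 0.09, the transcription factor Tfap2c at 1.66 ± 0.09 and the homeobox gene Rhox9 at 2.03 ± 0.12, and Eomes was among the falls. In the list of surface ectoderm and epithelial keratins 9 of 16 members rose and none fell (10 adjusted over the list alone; adjusted p = 0.00016, and adjusted p = 0.154 with an estimated correlation). Besides Krt7, which is in both lists, the tight junction gene Cldn4 rose by 0.84 ± 0.08 and Tfap2a by 0.70 ± 0.08. Targets of BMP rose for 10 of 17 members and fell for 1 (adjusted p = 0.00507, and adjusted p = 0.197 with an estimated correlation). Id3 rose by 1.08 ± 0.08, Gata2 by 1.25 ± 0.12 and Bmp4 itself by 1.58 ± 0.07.

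**Figure D3:**
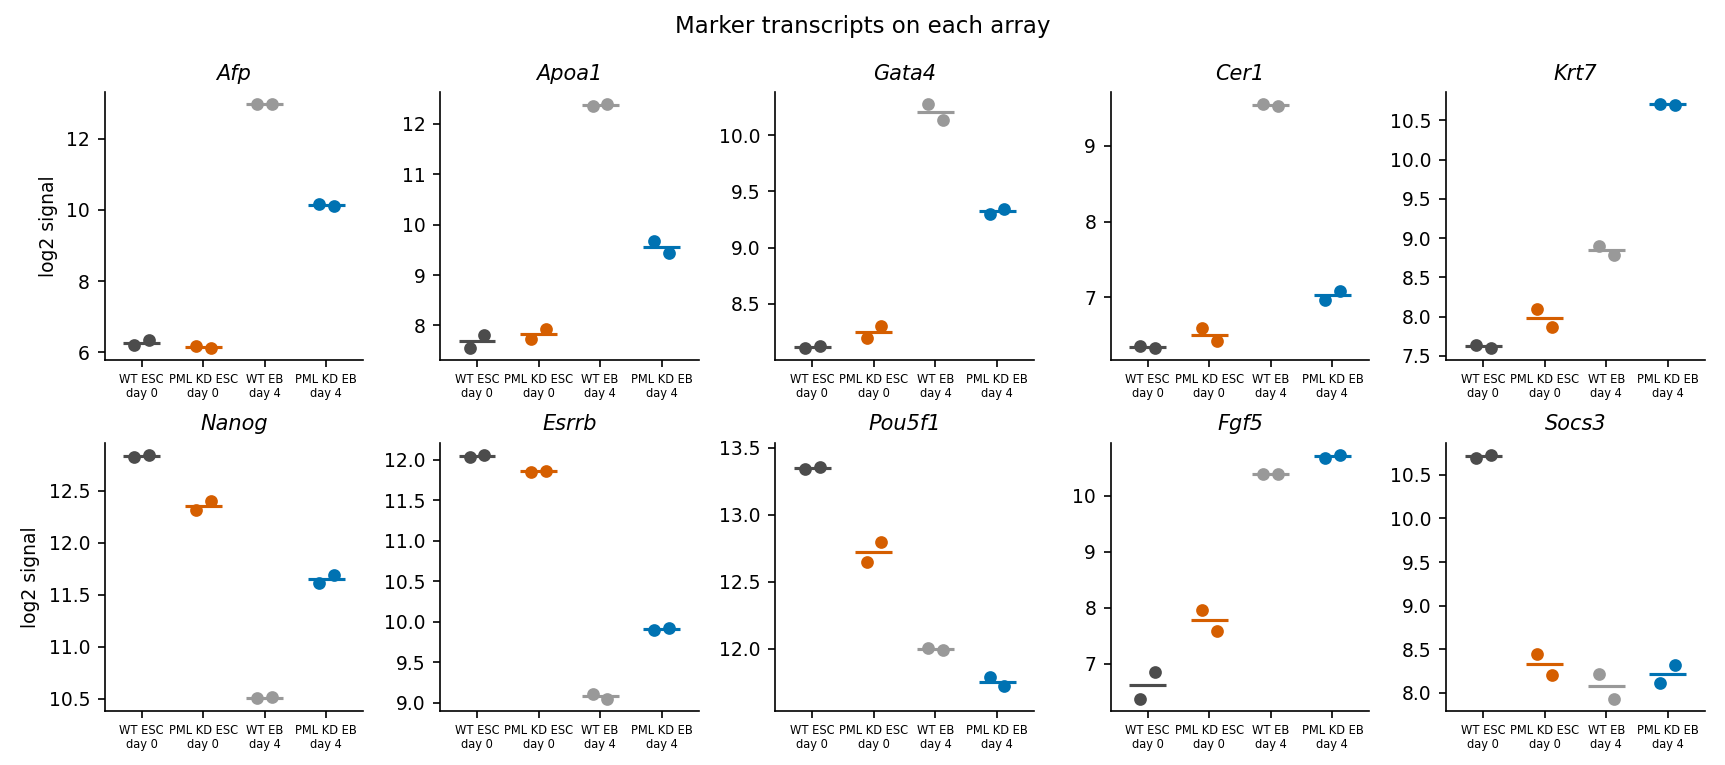
Log2 signal of 10 transcripts (vertical axes, each with its own range) on each array of the 4 groups, with a line at the mean of the 2 arrays. PML KD minus WT at day 4 was -2.82 for Afp, -2.81 for Apoa1, -0.88 for Gata4 and -2.51 for Cer1, and 1.86 for Krt7, 1.15 for Nanog and 0.83 for Esrrb.

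Cell cycle transcripts were higher in PML KD EBs, 28 of 41 members rising and none falling (31 adjusted over the list alone; camera, adjusted p = 1.32e-10, and adjusted p = 0.0959 with an estimated correlation). Ccnd3 rose by 1.11 ± 0.09, the ribonucleotide reductase subunit Rrm2 by 0.99 ± 0.08 and Mcm7 by 0.69 ± 0.08, together with the cyclin-dependent kinase inhibitor Cdkn1c, which restrains the cycle, by 0.81 ± 0.08. Glycolysis and hypoxia genes fell for 20 of 30 members and rose for 2 (21 and 2 adjusted over the list alone; adjusted p = 7.72e-07, and adjusted p = 0.06 with an estimated correlation). The phosphofructokinase Pfkp was at -1.15 ± 0.08, the prolyl hydroxylase P4ha1 at -1.16 ± 0.11 and the angiogenic factor Vegfa at -0.78 ± 0.07. In the TGF-beta and Nodal list 13 of 23 members rose and 4 fell (adjusted p = 0.00593, and adjusted p = 0.286 with an estimated correlation), led by the smooth muscle genes Acta2 (2.03 ± 0.10) and Tagln (1.63 ± 0.11). In the epithelial-mesenchymal transition list 11 of 25 rose and 2 fell (adjusted p = 0.00593, and adjusted p = 0.154 with an estimated correlation), among them the repressor Zeb2 (1.36 ± 0.08), which was at 0.62 (adjusted p = 0.192) in the workbook and lay under the 25th percentile of signal on both WT EB arrays. Fibroblast markers rose for 6 of 18 members and fell for 1, with the collagen Col1a2 at 2.06 ± 0.11 (adjusted p = 0.0439, and adjusted p = 0.46 with an estimated correlation). That call ended without WT EB replicate 1 (median 0.12, adjusted p = 0.0725) and without PML KD EB replicate 2 (median 0.09, adjusted p = 0.0711). Of the HOX cluster genes 5 of 27 fell over all genes and none when adjusted over the list alone (median -0.19; adjusted p = 0.00593, and adjusted p = 0.46 with an estimated correlation). Kdr of the vascular lineage rose by 0.42 ± 0.12, and Pax6 and Nes of the neural lineage by 0.41 ± 0.07 and 0.76 ± 0.12. The call of Kdr ended without WT EB replicate 1 (0.29, adjusted p = 0.168) and without PML KD EB replicate 1 (0.32, adjusted p = 0.189). Fgf5 (0.31 ± 0.16), Otx2 (-0.13 ± 0.08), Dnmt3b (-0.24 ± 0.10), Mixl1 (0.16 ± 0.09), Mesp1 (-0.20 ± 0.11) and Sox1 (0.17 ± 0.11) did not pass. Of these, Dnmt3b passed after quantile normalization (-0.30, adjusted p = 0.0436) and without either PML KD ESC array (-0.24, adjusted p = 0.0497), Otx2 after quantile normalization (-0.23, adjusted p = 0.0496) and Fgf5 with only the 4 EB arrays in the fit (adjusted p = 0.0294).

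The largest rises of named genes in PML KD EBs were Ldoc1 (2.61 ± 0.10), Serpinb9e (2.50 ± 0.14), the neural tube gene Prtg (2.25 ± 0.10), the splicing regulator Mbnl3 (2.22 ± 0.12) and the placental gene Plac1 (2.18 ± 0.15). Serpinb9e lay under the 25th percentile of signal on both WT EB arrays, which limits the size of its rise. Among the 10 largest falls were also the small nucleolar RNAs Snord118 (-2.97 ± 0.09) and Snora33 (-2.44 ± 0.07). Of the 8 measured Y-linked genes 1 rose, Zfy1 (0.65 ± 0.10, and 0.78 with adjusted p = 0.0511 in the workbook), and none fell, and chromosomes 8 and 14 lay 0.009 and -0.002 from the others. At day 4, 5705 genes (28.6%) changed, 3354 higher and 2351 lower in PML KD, 347 of them at least 2-fold (230 higher and 117 lower). After a median shift 404 changed at least 2-fold (321 and 83), and in the workbook 748 did, or 649 after quantile normalization. The share of changed genes that were higher was 58.8% as deposited and 80.2% after a median shift (5028 higher and 1242 lower), which moved the median of all genes from -0.023 to 0.092. The count was 5858 without the PML KD day 0 arrays, and 3376 and 3535 without replicate 1 or replicate 2 of the PML KD EBs. The lists of naive pluripotency, TGF-beta and Nodal, epithelial-mesenchymal transition, fibroblast, HOX cluster and cholesterol synthesis genes did not pass after quantile normalization (camera, adjusted p from 0.0579 to 0.405).

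**Figure D4:**
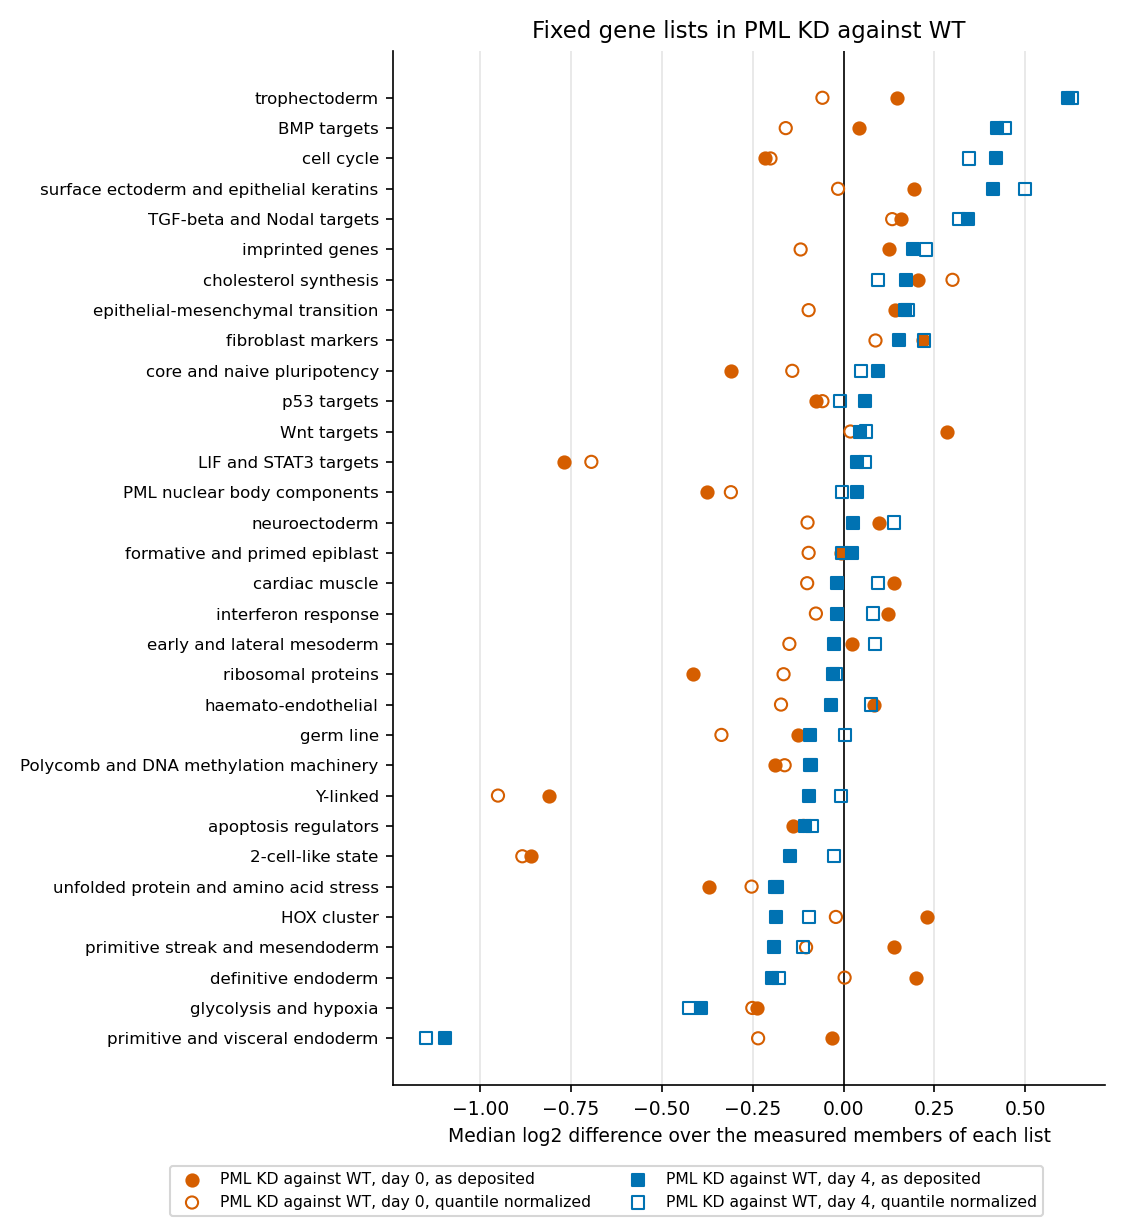
Median log2 difference between PML KD and WT (horizontal axis) over the measured members of 32 gene lists, at day 0 (circles) and day 4 (squares), as deposited (filled) and after quantile normalization (open). The primitive and visceral endoderm list lay lowest at day 4 (-1.10, and -1.15 after quantile normalization) and the 2-cell-like list lowest at day 0 as deposited (-0.86). After quantile normalization the Y-linked list was lowest at day 0 (-0.95, with the 2-cell-like list at -0.88).

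Differences at day 0 and at day 4, which share no arrays, were then compared. Over all changed genes fewer than expected by chance went the same way, 744 higher on both days (921 expected) and 468 lower on both (584 expected). More went opposite ways, 911 higher then lower (646 expected) and 1617 lower then higher (834 expected). These counts were made only on the deposited scaling, where trends with signal ran opposite ways at day 0 and day 4. The brightest of 10 groups by mean signal had medians of -0.247 and 0.137 (-0.078 and 0.061 after quantile normalization). The 4th group from the dim end had 0.225 and -0.078. How much of the excess comes from scaling was not tested. The correlation over all genes was -0.191, and -0.116 after quantile normalization. Among genes at least 2-fold different the counts were small. Both rises were seen for 8 genes (2.64 expected by chance; Fisher's exact test, p = 0.00523), and both falls for 3, Dab2, Eomes and Npl (4.07 expected; Fisher's exact test, p = 0.801). Falls at day 0 and rises at day 4 were seen for 21 genes (7.99 expected; Fisher's exact test, p = 5.67e-05), among them Ccnd3, Id3, Myc and Plagl1. The opposite order was seen for 6 (1.34 expected; Fisher's exact test, p = 0.00233). Both comparisons come from the same fit with a shared spread per gene, so their calls are not independent. The expected counts and Fisher p-values take them as independent, so an excess may come partly from genes that are easily called. Npl is named for the overlap of falls alone. Dab2 did not pass at day 4 in the workbook values after quantile normalization (-1.04, adjusted p = 0.0676).

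The course of differentiation was then followed in WT. All 36 measured primitive and visceral endoderm genes rose from day 0 to day 4, 32 of them at least 2-fold (median 3.15; camera, adjusted p = 2.98e-24, and adjusted p = 0.0284 with an estimated correlation). Afp rose by 6.70 ± 0.08, the thyroid hormone carrier Ttr by 6.48 ± 0.23, Apob by 6.01 ± 0.10 and the endocytic receptor Cubn by 5.07 ± 0.10. Core and naive pluripotency genes fell for 32 of 35 members and rose for 1 (median -1.66; adjusted p = 9.51e-19, and adjusted p = 0.0939 with an estimated correlation). Nr0b1 was at -4.11 ± 0.09, Esrrb at -2.97 ± 0.07, Zfp42 at -2.51 ± 0.07, Nanog at -2.33 ± 0.07 and Pou5f1 at -1.36 ± 0.08. LIF and STAT3 targets fell for 19 of 24 members and rose for 3 (adjusted p = 1.23e-07, and adjusted p = 0.0939 with an estimated correlation), with Egr1 at -4.21 ± 0.12 and Fos at -3.18 ± 0.07. Glycolysis and hypoxia genes rose for 24 of 30 and fell for 2 (adjusted p = 6.7e-09, and adjusted p = 0.0346 with an estimated correlation), with the lactate transporter Slc16a3 at 2.68 ± 0.07 and P4ha1 at 3.65 ± 0.11. Formative and primed epiblast genes rose for 17 of 26 and fell for 5 (adjusted p = 0.000898, and adjusted p = 0.185 with an estimated correlation), with Fgf5 at 3.76 ± 0.16.

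In the same WT cells 18 of 22 primitive streak genes rose and 1 fell, a count of rises that was 10 after quantile normalization (camera, adjusted p = 7.42e-05, and adjusted p = 0.277 with an estimated correlation). Cyp26a1 rose by 4.46 ± 0.11, Cer1 by 3.18 ± 0.08, Eomes by 0.87 ± 0.08 and Mixl1 by 0.32 ± 0.09, which after quantile normalization was 0.11 (adjusted p = 0.344). The call of Mixl1 also ended without WT ESC replicate 1 (0.34, adjusted p = 0.0523) or replicate 2 (0.30, adjusted p = 0.0776) and without WT EB replicate 1 (0.22, adjusted p = 0.103). Mesp1, at 0.38 ± 0.11 (adjusted p = 0.0188), was at -0.39 in the workbook values after quantile normalization and at 0.17 (adjusted p = 0.257) in the array table after it. It did not pass without WT ESC replicate 1 (0.25, adjusted p = 0.125) or WT EB replicate 1 (0.34, adjusted p = 0.086). Definitive endoderm genes rose for 11 of 16 and fell for 3 (adjusted p = 0.000898, and adjusted p = 0.0939 with an estimated correlation), Foxa2 by 1.15 ± 0.12 and Sox17 by 1.72 ± 0.19. Cell cycle genes fell for 27 of 41 and rose for 5 (adjusted p = 1.58e-05, and adjusted p = 0.141 with an estimated correlation), with Mcm6 at -1.45 ± 0.07. Unfolded protein and amino acid stress genes fell for 17 of 26 and rose for 7 (adjusted p = 0.00102, and adjusted p = 0.143 with an estimated correlation), with the transsulfuration enzyme Cth at -2.86 ± 0.08. Kdr (-0.03 ± 0.12), Sox1 (-0.05 ± 0.11), Pax6 (-0.14 ± 0.07) and Nes (0.14 ± 0.12) did not pass, although Nes was at -0.74 (adjusted p = 0.0429) and Kdr at -1.42 (adjusted p = 0.00642) in the workbook values after quantile normalization, and Pax6 at -0.35 (adjusted p = 0.00332) in the array table after it. In all 9946 genes (49.9%) changed in WT, 4849 higher and 5097 lower at day 4, 1473 of them at least 2-fold (632 and 841). After a median shift 1954 changed at least 2-fold (443 higher and 1511 lower), and in the workbook values after quantile normalization 2875 did. Afp, Cer1 and Cyp26a1 lay under the 25th percentile of the 19938 genes tested on both WT ESC arrays, which limits the size of their rises. The share of changed genes that were higher was 48.8% as deposited, 39.9% after quantile normalization and 23.0% after a median shift (2243 higher and 7513 lower), and the median of all genes was 0.059, -0.047 and -0.15.

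In PML KD cells the same course was followed from their own day 0 arrays, which differ from all others in Y-linked transcripts. Differences between the day 0 and day 4 cultures therefore cannot be told apart from changes during differentiation here. Visceral endoderm genes rose for 33 of 36 members (median 1.76; camera, adjusted p = 6.95e-18, and adjusted p = 0.026 with an estimated correlation). Cubn rose by 5.80 ± 0.10, Ttr by 4.58 ± 0.23, Afp by 3.98 ± 0.08 and Apob by 3.07 ± 0.10. Apoa1, at 1.73 ± 0.12 in the array table, was at -0.36 (adjusted p = 0.0124) in the workbook values after quantile normalization. Core and naive pluripotency genes fell for 29 of 35 members and rose for 4 (median -1.43; adjusted p = 2.24e-10, and adjusted p = 0.12 with an estimated correlation). Nr0b1 was at -2.33 ± 0.09, Esrrb at -1.95 ± 0.07, Pou5f1 at -0.97 ± 0.08 and Nanog at -0.71 ± 0.07. Glycolysis and hypoxia genes rose for 25 of 30 and fell for 2 (adjusted p = 2.75e-10, and adjusted p = 0.026 with an estimated correlation). Trophectoderm genes rose for 14 of 20 and fell for 2 (adjusted p = 6.51e-07, and adjusted p = 0.12 with an estimated correlation), Plac1 by 3.90 ± 0.15 and the imprinted gene Peg10 by 3.57 ± 0.08. LIF and STAT3 targets fell for 13 of 24 and rose for 7 (adjusted p = 0.11), and Fos fell by 0.31 ± 0.07, a call that ended after a median shift (-0.18, adjusted p = 0.0786). Of the Y-linked genes 4 of 8 rose and 1 fell, Eif2s3y by 4.85 ± 0.10 (adjusted p = 0.0165, and adjusted p = 0.131 with an estimated correlation). Chromosomes 8, 14 and X lay -0.252, -0.268 and 0.187 from the others, all outside the range of random gene sets. In WT over time chromosome 14 lay at -0.121, inside that range, and at -0.122 after quantile normalization, outside it. In all 9880 genes (49.6%) changed, 4847 higher and 5033 lower, 1587 of them at least 2-fold (1008 and 579), with 1742 after a median shift (1317 and 425) and 2921 in the workbook values after quantile normalization. Afp, Plac1 and Eif2s3y lay under the 25th percentile of signal on both PML KD ESC arrays, which limits the size of their rises. The share that were higher was 49.1% as deposited and 66.7% after a median shift (6290 and 3134), with the median of all genes at -0.059 as deposited, 0.043 after quantile normalization and 0.072 after the shift. The rises of at least 2-fold included 356 genes in both genotypes (32.0 expected by chance) and the falls 211 (24.4 expected). Opposite changes of that size were seen for 8 and 16 genes (18.4 and 42.5 expected). Over all changed genes 1841 rose (1180 expected) and 1851 fell (1290 expected) in both, 875 rose in WT and fell in PML KD (1220 expected) and 1516 fell in WT and rose in PML KD (1240 expected). The day 0 to day 4 comparisons share no arrays but come from the same fit. The expected counts take their calls as independent and are only a guide.

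The last comparison tested whether the change from day 0 to day 4 differed between PML KD and WT, as a difference of differences. It uses the PML KD day 0 arrays too and carries the same limit. Visceral endoderm genes rose less in PML KD: 27 of 36 differed downward and 2 upward (median -1.01; camera, adjusted p = 1.01e-07, and adjusted p = 0.24 with an estimated correlation). Apoa4 differed by -3.05 ± 0.14, Apoa1 by -2.95 ± 0.17 and Apob by -2.94 ± 0.14. LIF and STAT3 targets differed upward for 16 of 24 and downward for none (adjusted p = 4.31e-05, and adjusted p = 0.24 with an estimated correlation). Fos differed by 2.88 ± 0.10 and Socs3 by 2.53 ± 0.18, and both were low in PML KD ESCs at day 0. Core and naive pluripotency genes differed upward for 23 of 35 and downward for 6 (adjusted p = 0.00035, and adjusted p = 0.33 with an estimated correlation). Nanog differed by 1.62 ± 0.10, Esrrb by 1.02 ± 0.10 and Sox2 by 0.77 ± 0.11. Cell cycle genes differed upward for 29 of 41 and downward for 2 (adjusted p = 1.01e-07, and adjusted p = 0.24 with an estimated correlation), Ccnd3 by 2.23 ± 0.13 and Rrm2 by 1.49 ± 0.11. Mixl1 (0.11 ± 0.13), Mesp1 (-0.36 ± 0.15), Gata6 (-0.43 ± 0.22) and Sox1 (0.28 ± 0.16) did not pass. Gata6 passed without WT ESC replicate 2 (-0.62, adjusted p = 0.0447) or PML KD EB replicate 2 (-0.64, adjusted p = 0.0358) and Mesp1 without WT ESC replicate 2 (adjusted p = 0.0341). Mixl1 passed after quantile normalization (0.46, adjusted p = 0.0159) and Sox1 after a median shift (0.62, adjusted p = 0.0102). In the workbook values after quantile normalization Gata6 went the other way, at 0.58 (adjusted p = 0.0513). The Y-linked genes differed upward for 4 of 8, Eif2s3y by 4.88 ± 0.14, and the transcription factor Myc by 3.11 ± 0.16. In all 10089 genes (50.6%) differed, 5034 upward and 5055 downward, 2206 of them at least 2-fold (1609 and 597), with 2018 after quantile normalization (1463 and 555) and 3350 after a median shift (3146 and 204). The share upward was 49.9% as deposited, 65.1% after quantile normalization (5471 and 2933) and 83.8% after a median shift (8004 and 1547), with the median of all genes at -0.107, 0.092 and 0.233. HOX cluster genes differed downward for 14 of 27 and upward for none, with a median of -0.34 that was 0.01 after quantile normalization (adjusted p = 0.00549, and adjusted p = 0.423 with an estimated correlation). After quantile normalization 7 of the 13 lists that camera called passed, those of the 2-cell-like state, visceral endoderm, trophectoderm, BMP, LIF and STAT3, cell cycle and Y-linked genes.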

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

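The test of a delay in differentiation was planned before its result was seen. The spread of its result, its log2 form and the tests of the knockdown, of exchanged labels, of chromosomes 8 and 14, of scaling and of the share of cells were chosen only after the results were seen.

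The genes flagged here come from the limma test of whether the PML KD minus WT difference changed between day 0 and day 4. Each passed with a preset threshold of adjusted p under 0.05. The lists passed that threshold with camera at the preset correlation for the same contrast, and their values are medians over the members. In all 10089 of 19938 genes differed. By list, the median was -1.01 for primitive and visceral endoderm, -0.43 for primitive streak and mesendoderm, and -0.34 for the HOX cluster, where quantile normalization gave 0.01. It was 0.79 for the 2-cell-like state, 0.71 for Y-linked genes, 0.67 for cell cycle, 0.48 for LIF and STAT3 targets, 0.47 for trophectoderm, 0.46 for core and naive pluripotency, 0.44 for imprinted genes, 0.41 for PML nuclear body components, 0.37 for ribosomal proteins and 0.36 for BMP targets. The lowest adjusted p of camera with an estimated correlation was 0.24, so none of these 13 lists passed in that form. After quantile normalization the lists of PML nuclear bodies, pluripotency, primitive streak, imprinted genes, HOX cluster and ribosomal proteins did not pass.

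Among single genes, pluripotency factors differed upward: Nanog by 1.62, Esrrb by 1.02, Sox2 by 0.77, Zfp42 by 0.61, Klf4 by 0.39 and Pou5f1 by 0.38. Dnmt3b differed by 1.11 and Otx2 by 0.78, and Fgf5 by -0.84. Of lineage factors, Sox17 differed by -1.07, Gata4 by -1.02, Foxa2 by -0.65 and Pax6 by -0.47, and Nes by 0.77, Kdr by 0.53 and Eomes by 0.40. Pml itself differed by 0.36, since its difference was smaller at day 4. Quantile normalization ended the calls of Pml (adjusted p = 0.433), Pou5f1 (0.395), Klf4 (0.28), Pax6 (0.255), Foxa2 (0.0599) and Fgf5 (0.0537). In the workbook values after quantile normalization Zfp42 was at -0.73 (adjusted p = 0.0389) and Klf4 at -0.48 (adjusted p = 0.0806), and Srgn (0.26, adjusted p = 0.272), Otx2 (0.14, adjusted p = 0.438) and Eomes (0.28, adjusted p = 0.136) did not pass. There Sox17 was at -0.44 (adjusted p = 0.0551), Fgf5 at -0.32 (0.178), Pax6 at -0.19 (0.36), Pou5f1 at 0.20 (0.224) and Pml at 0.05 (0.755). A median shift ended the calls of Sox17 (-0.73, adjusted p = 0.0515), Fgf5 (-0.50, 0.115), Foxa2 (-0.31, 0.156) and Pax6 (-0.13, 0.319). Leaving out 1 array ended more calls. For Kdr this was WT ESC replicate 1 (0.42, adjusted p = 0.0982), WT EB replicate 1 (0.39, 0.0958), PML KD ESC replicate 1 (0.56, 0.0624) or 2 (0.50, 0.0805) and PML KD EB replicate 1 (0.43, 0.112). For Eomes it was WT ESC replicate 2 (0.38, 0.0525) and PML KD EB replicate 2 (0.36, 0.0538), and for Fgf5 PML KD ESC replicate 1 (-0.66, 0.0579) and PML KD EB replicate 1 (-0.82, 0.0533). Klf4 lost its call without 6 of the 8 arrays (all but WT EB replicate 1 and PML KD ESC replicate 2, 0.29 to 0.42, adjusted p from 0.0524 to 0.0973). Pml lost it without either WT ESC array or replicate 2 of any other group (0.29 to 0.36, 0.0516 to 0.0833), and Pou5f1 without either WT ESC array or replicate 1 of either PML KD group (0.31 to 0.39, 0.0512 to 0.0693). The Y-linked list lost its call without WT ESC replicate 1, PML KD ESC replicate 2 or replicate 2 of either EB group (median 0.59 to 0.77, 0.055 to 0.0583). Of named genes, the 10 largest upward differences were Eif2s3y (4.88), Spink10 (4.40), AU015836 (3.78), Tuba3a (3.51), Uty (3.45), Nup62cl (3.31), Klhl13 (3.22), Srgn (3.15), Myc (3.11) and Tdpoz3 (3.05). The 10 largest downward differences were Snord118 (-3.81), Kansl1 (-3.69), Snora33 (-3.54), Prss12 (-3.29), Snora75 (-3.28), Apoa4 (-3.05), Apoa1 (-2.95), Apob (-2.94), Adam4 (-2.81) and Ntn1 (-2.77).

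On the PML KD day 0 arrays 4 of 8 Y-linked transcripts were lower and chromosome 8 and 14 genes raised, and every comparison that uses these arrays carries this. Eif2s3y, Uty and Zfy1 lay at 4.95 to 5.77 there, under the 25th percentile of these arrays, so the size of their falls is limited by the signal range, while Uba1y fell only to 7.26 and 7.33. Kdm5d, Zfy2 and Usp9y lay under the 25th percentile on every array, WT included, so they could not show a fall. Sry, at 8.52 and 8.14 on the PML KD day 0 arrays, did not fall. The Y-linked genes that fell at day 0 had a median difference of -0.22 at day 4. Pml itself was only at -0.24 there, a call that was lost when any 1 of the 8 arrays was left out. With the knockdown so weakly seen at day 4, this test cannot decide whether the knockdown itself was the cause. The lowest correlation within a group (0.9955) lay 0.0127 above the highest between arrays of different groups, which argues against the exchange of 1 array with another group. The Y-linked signals cannot decide an exchange of both arrays, since 2 arrays stay low under any labels. Other values left it open for 0 of the 3 other groups: Pml was at -0.60 in PML KD at day 0, and the lower quartile of the visceral endoderm list over time was 0.67 in PML KD and 1.97 in WT. With chromosome 8 in 4 stretches of genes by position, the lowest lay 0.199 above other chromosomes. Of the stretches 3 passed the bound set first (above all 1000 random sets) and 4 the bound set next (above their middle 95%). A full extra copy in every cell would give 0.58 if signal followed copy number in proportion, which was not tested. For chromosome 14 the stretches ran from 0.003 to 0.327, with 3 above the middle 95% of random sets and 2 above all of them. The lowest goes against a gain of equal size along the whole chromosome, and a gain of part of it stays open. The rule used here differed from that for chromosome 8, under which chromosome 14 would be undecided. Chromosome 14 also lay at -0.121 in WT over time. A candidate explanation is a day 0 culture with less of these Y transcripts and with extra chromosome 8 that the day 4 culture lacks. Whether all or part of the day 0 cells would carry it cannot be told from these values. A sample from another culture stays open, as no array outside the study was compared.

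Visceral endoderm transcripts were lower in PML KD EBs. Scaling between arrays as the cause is argued against by the median of -1.15 after quantile normalization. Of the 26 members that rose at least 4-fold in WT, the fraction of the linear gain kept ran from 0.053 (Apoa4) to 0.889 (Dkk1), a span of 0.84, and Cubn (0.504) and Amn (0.19), which act as a receptor pair, also lay apart. This argues against a loss of cells that express all members alike as the whole cause, if signal follows RNA amount in proportion. It cannot exclude a smaller share of visceral endoderm cells as part of the cause. Nor can it exclude this as the whole cause where those cells differ in these members. The span rests on its extreme members, and members such as Dkk1 are also expressed elsewhere. For a delay of the whole programme the median kept fraction was 0.324 in the list (quartiles 0.202 and 0.479) and 0.562 in 132 other risers (0.36 and 0.868). They lay 0.24 apart, above the 0.2 set against a delay, but the 95% bootstrap interval ran from 0.102 to 0.383. As fractions of the log2 change the medians were 0.593 and 0.749. Of the other risers 91 were lower and 15 higher in PML KD EBs, and of 85 genes that fell at least 4-fold in WT 40 were higher and 8 lower. All of these sets were chosen by their change in WT and then compared with the same WT EB arrays. That choice favours lower values in PML KD for risers and higher ones for fallers. It also leaves out genes that changed only in PML KD, so these counts cannot speak for a delay. These 85 kept a median of 0.901 of their log2 fall (quartiles 0.72 and 1.013), which goes against a delay that holds all genes back alike, although genes that reach their low level early would keep theirs under a delay. A delay and a change particular to the visceral endoderm therefore cannot be told apart, as the spread includes smaller differences than the level set and no day between was measured. The knockdown was not tested apart from differences between the cultures. Independent knockdown cultures sampled on several days would be needed to separate these.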

How the results depend on the processing

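The fit without the PML KD day 0 arrays was chosen only after the data were seen. All else was planned. The counts of changed genes, their higher and lower parts and their parts changed at least 2-fold (20 results) stayed within 1.5 times in 353 of 382 comparisons with alternatives. For the counts of all changed genes the exceptions come from the threshold or from fewer arrays. With at least 2-fold they were 922 (day 0), 347 (day 4), 1473 (WT over time), 1587 (PML KD over time) and 2206 (difference of changes), and at adjusted p under 0.01 they were 3085 at day 4 and 6653 for the difference of changes. The other exceptions are in the parts. A median shift moved 8: at day 0 the higher part to 2032 and the 2-fold part to 1550, at day 4 the lower part to 1242, in WT over time the higher part to 2243, in PML KD over time the lower part to 3134, and for the difference of changes the upward, downward and 2-fold parts to 8004, 1547 and 3350. Quantile normalization moved the higher part at day 0 to 3379 and the downward part of the difference of changes to 2933, which was 3275 with genes above the median signal. The workbook moved the 2-fold part at day 4 to 748 (649 after quantile normalization), and after it those of WT and PML KD over time to 2875 and 2921. Without PML KD EB replicate 1 the parts at day 4 were 2163 higher and 1213 lower, without replicate 2 they were 2146 and 1389, and without WT EB replicate 2 the lower part was 1442. Leaving out 1 array, with the lone array of its group taken to vary like the others, gave 7971 to 10484 at day 0, 7637 to 10098 in WT over time, 7553 to 9942 in PML KD over time and 8175 to 9964 for the difference of changes. At day 4 it gave 3376 (without PML KD EB replicate 1; 3535 without replicate 2) to 5858. Without both PML KD day 0 arrays 5858 genes changed at day 4, 5487 of them shared with the 5705, and 10098 in WT over time (9713 shared). With the replicate block the counts were 10347, 5395, 9859, 9726 and 9941, and Pml at day 0 was -0.601 (adjusted p = 0.00091).

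The fall of Pml at day 4 lost its call at -0.23 (adjusted p = 0.118) in the workbook, at -0.129 (0.246) after a median shift, and at -0.244 with only the 4 samples (0.083), with the replicate block (0.0614) and without the PML KD day 0 arrays (0.0532), where fewer degrees of freedom remain. It kept its call at -0.338 (0.0145) after quantile normalization and at -0.348 (0.0314) in the workbook after it. Leaving out 1 array gave -0.315 (without PML KD EB replicate 2) to -0.172 (without replicate 1), with adjusted p from 0.0527 to 0.243. Of 234 gene results, 8 turned direction with a call before or after, all in the workbook after quantile normalization unless noted: at day 0 Klf4 (0.069) and Sox17 (-0.421), at day 4 Zfp42 (-0.264, and -0.159 as deposited), in WT over time Mesp1 (-0.387) and Nes (-0.742), in PML KD over time Apoa1 (-0.363), and in the difference of changes Klf4 (-0.482) and Zfp42 (-0.727). The cause was not tested. A further 27 comparisons of 16 gene results changed sign with no call in either fit, for 8 of these results when 1 array was left out. Of 4398 such comparisons 100 lost a call and 31 gained one. Of 160 list results, fry turned the direction of trophectoderm at day 0 (median 0.148) and interferon response in WT over time (0.084), where median and mean differ in sign. Many other list medians changed sign too, mostly after quantile normalization or a median shift and mostly with no call in either fit. Neuroectoderm at day 0, for instance, moved from 0.097 to -0.099 after quantile normalization. Cholesterol synthesis in WT over time moved from -0.039 to 0.122 after it and gained a call (camera, adjusted p = 0.0439). Fibroblast markers at day 0 moved from 0.22 to -0.005 after a median shift and lost theirs. In 2144 list comparisons 119 lost a call, 67 of them with an estimated correlation and 25 after quantile normalization, and 69 gained one, 50 of them with fry. The scan date was not run as a block. Signal range limits dim genes: the 25th percentile of all probe sets of an array lay at 6.09 to 6.38 on the log2 scale. Genes said to lie under the 25th percentile were compared with that of the 19938 genes tested on the same array.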

Other observations

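The test of the signal range was planned before its result was seen, and the lists here were fixed before the data were examined.

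Imprinted genes, which are expressed from 1 parental copy and shape growth of the embryo and placenta, went both ways at day 0, with 12 of 32 rising and 11 falling. The placental gene Peg10 fell by 1.58 ± 0.08 and the zinc finger gene Plagl1 fell by 1.56 ± 0.09. At day 4, 13 rose and 3 fell (camera, adjusted p = 0.00682, and adjusted p = 0.36 with an estimated correlation). Phlda2, a restraint on placental growth, rose by 1.99 ± 0.08, Mest by 1.64 ± 0.08 and Nnat by 1.42 ± 0.08, and the growth inhibitor Grb10 fell by 1.55 ± 0.07. Over time 18 of 32 rose and 5 fell in WT, and 23 rose and 4 fell in PML KD, with Igf2 at 4.79 ± 0.13 and 5.11 ± 0.13. Ifitm1, Ifitm2 and Ifitm3, membrane proteins that also mark early germ cells, rose in PML KD EBs by 1.39 ± 0.09, 1.15 ± 0.08 and 1.30 ± 0.09, while the interferon response list as a whole had 4 of 36 rising and 4 falling (adjusted p = 0.889). In the germ line list 3 of 26 rose and 3 fell, with the oocyte gene Dppa3 at 0.78 ± 0.10 and the meiosis gene Sycp3 at -1.06 ± 0.21, both of which did not pass in the workbook values (adjusted p = 0.126 and 0.0715).

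Stress and survival genes changed in both directions at day 4. Ddit3, a transcription factor of the unfolded protein response, fell by 0.97 ± 0.08 and Mthfd2 of mitochondrial folate metabolism fell by 0.66 ± 0.08, in a list with 10 of 26 falling and 4 rising (adjusted p = 0.0522, 0.00169 after quantile normalization, 0.0353 after a median shift and 0.0384 without PML KD EB replicate 1). Of 20 apoptosis regulators 5 rose and 6 fell, the initiator Casp8 by 1.38 ± 0.08 and the survival factor Mcl1 at -0.69 ± 0.07. Of 27 p53 targets 5 rose and 3 fell, with Pltp at 0.77 ± 0.08 and Pmaip1 at -0.75 ± 0.10. Of 20 cholesterol synthesis genes 9 rose and 2 fell (adjusted p = 0.0356, and adjusted p = 0.579 with an estimated correlation), with Nsdhl at 0.69 ± 0.08, and the list lost its call without WT EB replicate 1 (median 0.13, adjusted p = 0.0859). Mesodermal lists had no common direction: early and lateral mesoderm 7 rising and 9 falling of 33, cardiac muscle 4 and 3 of 21, and haemato-endothelial genes 8 and 4 of 26, with the embryonic globin Hbb-bh1 at 1.05 ± 0.10 (under the 25th percentile of signal on all 4 EB arrays) and the notch ligand Dll1 at -1.07 ± 0.13. In the neuroectoderm list 9 of 30 rose and 1 fell, Msi1 by 0.80 ± 0.09, and in the Wnt list 3 of 17 rose and 2 fell. None of the lists of mesoderm, cardiac muscle, blood and vessels, neuroectoderm, Wnt, p53, apoptosis or germ line passed with camera at day 4 (adjusted p from 0.466 to 0.902).

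In the PML KD ESCs dim genes were higher and bright genes lower: with genes in 10 groups by mean signal, the median difference reached 0.225 among dim genes and -0.257 among bright genes. A like trend was seen in WT over time, to 0.197 among dim genes and -0.288 among bright genes. Both comparisons are against the WT ESC arrays, which had the widest signal range (between quartiles, 3.143 and 3.184). Probes that the platform table does not list can tell a change in the signal range of the arrays from a change in named genes. The 4276 dim unlisted probes had a median of 0.34 and the 5507 dim named genes one of 0.205, farther apart than the 0.05 set for that explanation and not below the level set against it, so the signal range of the arrays and a change in expression cannot be told apart. After quantile normalization the medians of the 10 groups in PML KD ESCs lay between -0.034 and -0.102. No biological explanation was tested for this pattern.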
